A study of Homo sapiens with 6 samples.

How the data were processed

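Gene expression was measured on 6 one-colour Affymetrix oligonucleotide arrays hybridised with biotin-labelled cRNA made from 6 ug of total RNA. Each array carried RNA from SW480, an established human colon carcinoma cell line. Per the labels, 3 arrays came from cells given a non-targeting short hairpin RNA (shRNA) and 3 from cells given an shRNA against gankyrin for 4 days. The array type is taken from the platform line of the probe annotation, which names the Affymetrix Human Genome U133 Plus design by its platform code. Groups and replicate numbers were taken from the sample titles. One sentence of the series design names NFIL3 in place of gankyrin for the knockdown; the titles, sources and genotype labels all name gankyrin, so both genes were examined on every array. The labels do not say whether the replicates came from separate cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical.

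The deposited values are log2 probe set signals, 1 per probe set and array, for 54675 probe sets, of which 62 are manufacturer's control probe sets. The log2 scale is read from the values themselves, which run from 1.29 to 13.68 and would exceed any scanner's range on another base. Per the submitters' processing notes the tool was MAS5, whose role and version are not given in the sources used here. The values have a floor near 2 with little scatter, which is more like a model-based summary than the logarithm of MAS5 signals, so the summary method is left open. The arrays had already been brought to 1 scale: their medians lay between 4.20 and 4.25. No detection calls were used here, so no probe set is described as absent. For arrays the number of replicates, 3 per group, limits the precision. No sample column was left unmapped.

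Gene names came from the platform annotation of the probe sets, updated through Entrez gene identifiers to the symbols of the RefSeq annotation of GRCh38.p14. Of the probe sets other than controls, 41091 were paired with 1 gene, 1801 with several and 11721 are not named here. Of the single genes, 19735 matched the RefSeq table and 42 kept the older symbol. No genome build is given in the sources used here, and no coordinates are reported. Control probe sets and the lowest 40% of the other probe sets by mean over all 6 arrays (limit 3.6 on the log2 scale) were left out, which left 32759. Each gene was represented by its brightest single-gene probe set, giving 14199 genes. As a description of the low end of the scale, the 95th percentile of the mean signals of 45 probe sets for tissue-restricted genes, such as olfactory receptors and lens crystallins, was 4.31.

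The deposited log2 values were used without further normalization. Knockdown and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. "Rose" and "fell" are used only for genes past that threshold. A set of 38 gene lists, fixed before the data were examined together with the comparison, the alternatives and the rule for naming genes, was tested with limma's camera (preset inter-gene correlation of 0.01, lists of at least 4 measured genes), with adjustment over the 38 lists. With a preset correlation, camera compares the genes of a list with all other genes and takes its degrees of freedom from the number of genes. Its p-values at that setting therefore do not measure the spread between arrays. With an estimated correlation the degrees of freedom are the few of the arrays, so a gap between the settings does not measure correlation alone. The lists hold standard members of each pathway or cell type, and none was chosen on these arrays. They comprise proteasome subunits and assembly chaperones, p53 targets, E2F targets, G2/M genes, CDK inhibitors with the RB family, Wnt, NF-kB, STAT3, YAP, TGF-beta, NRF2, ATF4 and MAPK target genes, PI3K/AKT/FOXO genes, enterocyte, epithelial and mesenchymal genes, interferon, antigen presentation, hypoxia, glycolysis, unfolded protein, heat shock, cholesterol, fatty acid, ribosomal protein, ribosome biogenesis, respiratory chain, apoptosis, autophagy, histone and RNAi machinery genes, and markers of fibroblasts, leukocytes, endothelium and liver as other cell types; 1 further list was tested with them, counts among the 38 and is not reported here. Genes were named by this rule: PSMD10 and NFIL3; the 12 largest rises and 12 largest falls among called genes whose 3 knockdown values all lay on one side of the 3 control values; up to 4 members of smallest p from each list past the threshold; and up to 2 from each other list.

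The pipeline was tested on simulated data for 14199 genes with the observed means and within-group spread, in which known genes were changed. It recovered 11 of 50 genes changed by 0.3 on the log2 scale, 28 of 50 changed by 0.5, 46 of 50 changed by 1 and 50 of 50 changed by 2, and 4 of its 139 calls were unchanged genes. A simulated shift of 0.2 in the proteasome list was called, and 0 other lists were. Far fewer genes were called in the simulation than the 3189 of the real comparison, which makes the adjustment stricter. Its recovery rates therefore do not carry over directly to the real comparison. The simulated genes varied independently of each other. The simulation therefore could not show false list calls that come from correlation within a list. Alternatives covered quantile normalization, median centring, the filter on dim probe sets, the variance model, the choice of probe set per gene, the replicate number as a block, array weights, the threshold, the set test and leaving out each array in turn, and 10000 random lists matched on mean signal were drawn for each list. Pseudocounts were not varied because the deposited values are already logarithms. No 2 arrays held identical values. Figures were drawn with matplotlib 3.10.9.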

Results

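Gene expression after loss of gankyrin was profiled in SW480 colon carcinoma cells. Gankyrin, the product of PSMD10, is an ankyrin-repeat protein that acts as an assembly chaperone of the proteasome's regulatory particle and binds the retinoblastoma protein and CDK4. Cells carried either a non-targeting control shRNA (n = 3 arrays) or an shRNA against gankyrin (n = 3 arrays) for 4 days. The 6 arrays had median log2 signals of 4.20 to 4.25, and each array's mean correlation with the others of its group was between 0.993 and 0.998 across genes.

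PSMD10 was far lower on every knockdown array. On its brighter probe set the log2 signal was 10.19, 10.23 and 10.15 in control replicates 1 to 3 and 6.58, 6.47 and 6.30 in knockdown replicates 1 to 3. PSMD10 fell 13.4-fold (log2 fold change -3.74 ± 0.08 SE), with the smallest p of the 14199 genes tested (limma, adjusted p = 6.81e-09). The dimmer PSMD10 probe set went from 9.51 ± 0.41 to 6.55 ± 0.10 (SD, n = 3 each). NFIL3, a basic leucine zipper repressor that 1 sentence of the series design names as the target, was at 9.33 ± 0.13 in control and 9.07 ± 0.05 in knockdown arrays (SD, n = 3 each). The log2 fold change of NFIL3 was -0.26 ± 0.07 SE (limma, adjusted p = 0.0281). It missed the threshold without control replicate 2 (adjusted p = 0.0630) and without knockdown replicate 1, 2 or 3 (adjusted p = 0.0661, 0.0967 and 0.112). An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 for each gene, the smallest value this design allows. PSMD10 thus matched the gankyrin labels on all 6 arrays.

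Expression differed between knockdown and control arrays for 3189 of 14199 genes at an adjusted p under 0.05 in limma. Of these, 1154 rose and 2035 fell. The median absolute log2 fold change of the called genes was 0.39, and 119 genes changed at least 2-fold, 37 upward and 82 downward. Leaving out knockdown replicate 1, 2 or 3 lowered the total to 1734, 1743 or 1732 genes. Values of the 2 groups did not overlap for 5717 genes, or 40.3%. Over all splits of the arrays, 3 against 3, this share averages 10%. Genes on an array can vary together, so the share of a single split can lie far from that average. Centring each array on its median raised the share of called genes that were higher from 36.2% to 48.8%, and quantile normalization gave 40.9%, so the size of the excess of falling genes depends on the scaling. Across all genes the median log2 fold change was -0.02, and no scaling moved it by over 0.1.

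The deepest fall belonged to FGL1, a secreted fibrinogen-like protein and ligand of the immune receptor LAG3, which fell 19.5-fold from 8.41 ± 0.13 to 4.13 ± 0.35. MMP10, the matrix metalloproteinase stromelysin-2, fell 6.60-fold, and GULP1, an engulfment adaptor, fell 6.47-fold. ACOT4, a peroxisomal acyl-CoA thioesterase, fell 5.98-fold, and AKAP12, a scaffold of protein kinase A, fell 5.67-fold from a high control level of 11.73 ± 0.12. DHRS2 (a short-chain dehydrogenase), the cytokine IL32, the phospholipid transfer protein PLTP and ANKRD29 fell by 5.44-, 5.28-, 4.98- and 4.70-fold. AHNAK2 fell 4.01-fold on one probe set, while its second, dimmer probe set changed by 0.18 on the log2 scale and did not pass. NRP1, a co-receptor for semaphorins and VEGF, fell 3.85-fold. The knockdown means of FGL1, ACOT4 and AHNAK2 lay below the 4.31 that bounds 95% of the probe sets of tissue-restricted genes. All of these had adjusted p-values of at most 7.4e-05 (limma, n = 3 per group).

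Among the largest rises were NEB (nebulin) at 3.42-fold, ARHGAP6, a GTPase-activating protein, at 3.22-fold, and the annexin ANXA13 at 3.15-fold. SPP1 (osteopontin) rose by 1.58 on the log2 scale, from 7.49 ± 0.30 to 9.07 ± 0.06. MATN2 (a matrilin of the extracellular matrix), ANGPT1 (a ligand of the receptor TIE2), RETREG1 (a receptor for autophagy of the endoplasmic reticulum) and AADAC (arylacetamide deacetylase) rose by 2.82-, 2.75-, 2.69- and 2.68-fold. HPGD, which degrades prostaglandins, rose 2.61-fold and on all 4 of its probe sets past the filter. FERMT2 (kindlin-2) rose 2.51-fold. UGT1A6, a glucuronosyltransferase whose probe set can be shared by the UGT1A isoforms, and the lactate receptor HCAR1 also passed, with 3.69- and 2.55-fold rises. Both calls were lost without knockdown replicate 1, 2 or 3 (limma adjusted p = 0.0678, 0.0737 and 0.0724 for UGT1A6; 0.133, 0.118 and 0.106 for HCAR1) and with a robust variance prior (0.150 and 0.155). Both of those sizes rest on a low value in control replicate 3. Without it the log2 fold changes went from 1.88 to 1.13 for UGT1A6 and from 1.35 to 0.71 for HCAR1. Both rises still passed without that array, at limma adjusted p-values of 4.20e-09 for UGT1A6 and 6.09e-05 for HCAR1.

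**Figure D1:**
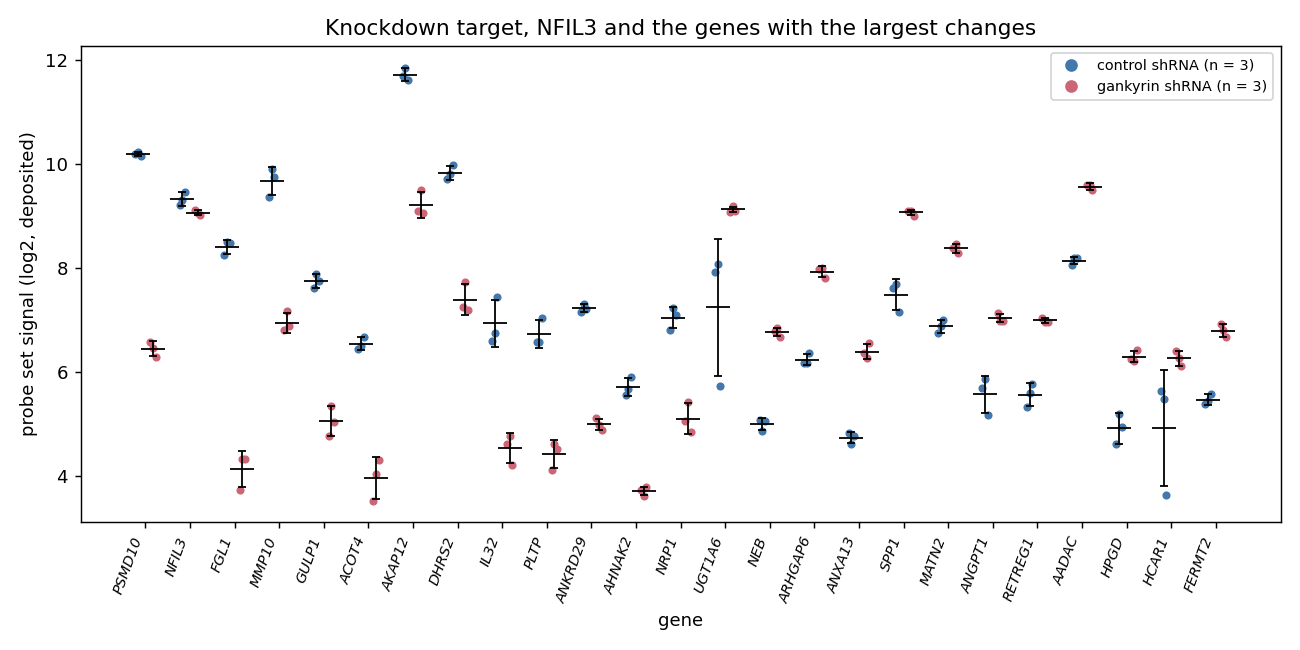
Log2 probe set signal (y axis) of PSMD10, NFIL3 and the genes with the largest falls and rises (x axis) on each array; points are arrays, blue for control and red for gankyrin shRNA, and black marks are the mean with SD (n = 3). PSMD10 fell from 10.19 to 6.45 while NFIL3 went from 9.33 to 9.07, and the UGT1A6 and HCAR1 controls are spread by 1 low array.

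Of the 38 gene lists, 17 passed camera with its preset correlation, 5 of them higher and 12 lower after knockdown. All 17 kept their direction and call without control replicate 3, and 0 of the 17 passed when camera estimated the inter-gene correlation from these 6 arrays (3 lists at an unadjusted p under 0.05; limma's fry, which tests a list on its own, called 22). The 18S ribosomal RNA control probe sets were also higher after knockdown, by 0.79 to 1.29 on the log2 scale. Any measure that differs between the groups does so alongside every called list, so no link follows from this. Their relation to the lists within a group was not tested. Cholesterol synthesis genes were the list of smallest p. Of 19 measured members 11 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median log2 fold change of 0.32 (camera adjusted p = 1.61e-07, adjusted p = 0.447 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, rose by 0.83 ± 0.06 (log2 ± SE), the farnesyl diphosphate synthase FDPS by 0.51 ± 0.05, the sterol carrier STARD4 by 0.60 ± 0.07 and the sterol isomerase EBP by 0.57 ± 0.10 (0.28 with its probe sets averaged). Of 26 respiratory chain genes 14 rose and 0 fell (15 and 1 adjusted over the list alone), by a median of 0.15 (camera adjusted p = 3.47e-06, adjusted p = 0.447 with an estimated correlation). They included the ATP synthase subunit ATP5F1A (0.33 ± 0.04), cytochrome c1 CYC1 (0.58 ± 0.07) and the succinate dehydrogenase subunit SDHA (0.46 ± 0.07). ATP5F1C, also past the threshold at 0.24 ± 0.04, was at -0.29 and did not pass on a probe set whose name does not end in _x_at or _s_at.

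Subunits of the 26S proteasome, the complex that gankyrin helps to assemble, were slightly higher. Of 29 measured subunits 11 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 4.66e-06, adjusted p = 0.452 with an estimated correlation). PSMA2 rose by 0.34 ± 0.06, PSMA1 by 0.28 ± 0.05, PSMB3 by 0.20 ± 0.04 and the ATPase PSMC1 by 0.24 ± 0.05; the PSMB3 call was lost with no intensity trend in the variance (limma adjusted p = 0.0650). Of the 9 other proteasome assembly chaperones 0 passed in limma, over all genes or over the list alone (1 at an unadjusted p under 0.05), and their list did not pass either (median 0.02, camera adjusted p = 0.472). Without control replicate 3, 1 of these chaperones rose. NRF2 targets, genes of detoxification and redox balance, were higher: 14 of 22 rose and 2 fell (14 and 4 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 4.66e-06, adjusted p = 0.447 with an estimated correlation). The aldo-keto reductase AKR1B10 rose by 1.23 ± 0.08. AKR1C1, AKR1C2 and AKR1C3 rose by 0.90 ± 0.05, 0.99 ± 0.05 and 0.90 ± 0.06, and these near-identical genes may share probes. Dimmer AKR1C1 probe sets past the filter were at 0.94, 0.45 and -0.03, the last of which did not pass. Of 32 E2F target and G1/S genes 12 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 2.07e-05, adjusted p = 0.452 with an estimated correlation). The replication factor CDC45 rose by 1.04 ± 0.08, GINS2 by 0.54 ± 0.08, the ribonucleotide reductase subunit RRM2 by 0.34 ± 0.05 and the chromatin assembly factor CHAF1B by 0.47 ± 0.08. The GINS2 call was lost when its probe set ending in _s_at or _x_at was avoided. Of 32 G2/M genes 1 rose and 5 fell, as many as adjusted over the list alone, and that list did not pass (median 0.03, camera adjusted p = 0.909). Without control replicate 3 the G2/M counts were 3 rises and 5 falls.

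Target genes of inflammatory signalling and genes of antigen presentation were lower as lists. Of 15 NF-kB target genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00284, adjusted p = 0.452 with an estimated correlation). The chemokines CXCL8, CCL20 and CXCL1 changed by -1.15 ± 0.08, -1.59 ± 0.17 and -1.23 ± 0.17, and the adhesion molecule ICAM1 by -0.63 ± 0.08. Of 17 STAT3 target genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0117, adjusted p = 0.529 with an estimated correlation). FGL1 led this list, followed by the lipocalin LCN2 at -1.52 ± 0.19 and the metalloproteinase inhibitor TIMP1 at -0.31 ± 0.05; the list's call was lost when a gene's probe sets were averaged (adjusted p = 0.113). Of 15 antigen presentation and immunoproteasome genes 6 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00105, adjusted p = 0.529 with an estimated correlation). The class I genes HLA-B, HLA-E, HLA-C and HLA-F changed by -0.46 ± 0.05, -0.47 ± 0.05, -0.36 ± 0.05 and -0.25 ± 0.06, with probes that class I genes can share. Of the probe sets past the filter, 1 of 3 for HLA-B, 3 of 3 for HLA-E, 3 of 4 for HLA-C and 1 of 3 for HLA-F passed as lower. The HLA-F call was lost without control replicate 2 (limma adjusted p = 0.0632), without knockdown replicate 1 (0.0802) or 3 (0.0629), and when probe sets ending in _x_at or _s_at were avoided (0.158).

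Genes of cell adhesion and of growth factor signalling were also lower as lists. Of 23 epithelial adhesion genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00107, adjusted p = 0.452 with an estimated correlation). The desmosomal genes DSP and DSC2 fell, at -0.83 ± 0.05 and -0.92 ± 0.10, as did CLDN3 at -0.51 ± 0.06, while the tight junction gene CLDN1 rose by 0.97 ± 0.08. The CLDN3 call was lost when its probe sets were averaged (-0.36, limma adjusted p = 0.0946). Of 17 YAP/TEAD targets 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00122, adjusted p = 0.529 with an estimated correlation). They included NT5E (-0.92 ± 0.07), DOCK5 (-1.12 ± 0.11) and the matricellular gene CCN1 (-0.85 ± 0.10). The 3 other NT5E probe sets past the filter, at -0.22, -0.22 and -0.44, did not pass; with probe sets averaged NT5E was at -0.45 and DOCK5 at -0.67. Of 17 TGF-beta/SMAD targets 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.00852, adjusted p = 0.529 with an estimated correlation). PMEPA1 and the collagen gene COL4A1 fell, at -0.87 ± 0.07 and -1.14 ± 0.13, whereas BAMBI and ID2 rose by 0.63 ± 0.05 and 0.62 ± 0.07. The knockdown mean of COL4A1, 3.87, lay below the low-end value of 4.31, so the size of its fall is uncertain. The TGF-beta call was lost when the lowest 60% of probe sets were left out (adjusted p = 0.0575) and when a gene's probe sets were averaged.

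MAPK feedback genes were lower in 8 of 20 cases and higher in 0 (8 and 1 adjusted over the list alone, 8 and 2 without control replicate 3), with a median of -0.18 (camera adjusted p = 0.0233, adjusted p = 0.529 with an estimated correlation). The cyclin CCND1 was at -1.09 ± 0.10, the AP-1 subunit FOSL1 at -0.97 ± 0.10 and the receptor EPHA2 at -0.52 ± 0.08. This list mixes feedback inhibitors such as the DUSP and SPRY genes with other MAPK target genes, and the named members belong to the latter. A change in feedback itself was not tested. Among 22 PI3K/AKT/FOXO genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00849, adjusted p = 0.546 with an estimated correlation). The insulin receptor substrates IRS2 and IRS1 fell, at -1.27 ± 0.12 and -0.60 ± 0.10, and the regulatory subunit PIK3R1 rose by 0.81 ± 0.07. Among 20 hypoxia-responsive genes 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00207, adjusted p = 0.529 with an estimated correlation). BNIP3L, the peptide hormone ADM and NDRG1 were at -0.68 ± 0.06, -0.93 ± 0.12 and -0.99 ± 0.14. Among 24 genes of the unfolded protein response 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0172, adjusted p = 0.529 with an estimated correlation). MANF was at -0.50 ± 0.08 and the chaperones HYOU1 and HSPA5 at -0.37 ± 0.06 and -0.27 ± 0.06, HSPA5 not passing with no intensity trend (limma adjusted p = 0.0543). Among 9 replication-dependent histone genes 6 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0358, adjusted p = 0.452 with an estimated correlation). H2BC5, on probes that near-identical histone genes can share, was at -0.59 ± 0.07, and only 1 of its 2 probe sets past the filter passed. H1-4 was at 0.52 ± 0.12 from a low control mean of 4.10. How fully the labelled cRNA captured histone transcripts was not tested, so these values may not give their total level. The H1-4 call was lost without knockdown replicate 1 (limma adjusted p = 0.0656) or 2 (0.0531). The MAPK, unfolded protein and histone calls were lost without control replicate 2, at adjusted p-values of 0.0614, 0.0674 and 0.0636, and the histone call also without control replicate 1 (0.0646). The MAPK and unfolded protein calls were also lost when the lowest 60% of probe sets were left out or a gene's probe sets were averaged.

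**Figure D2:**
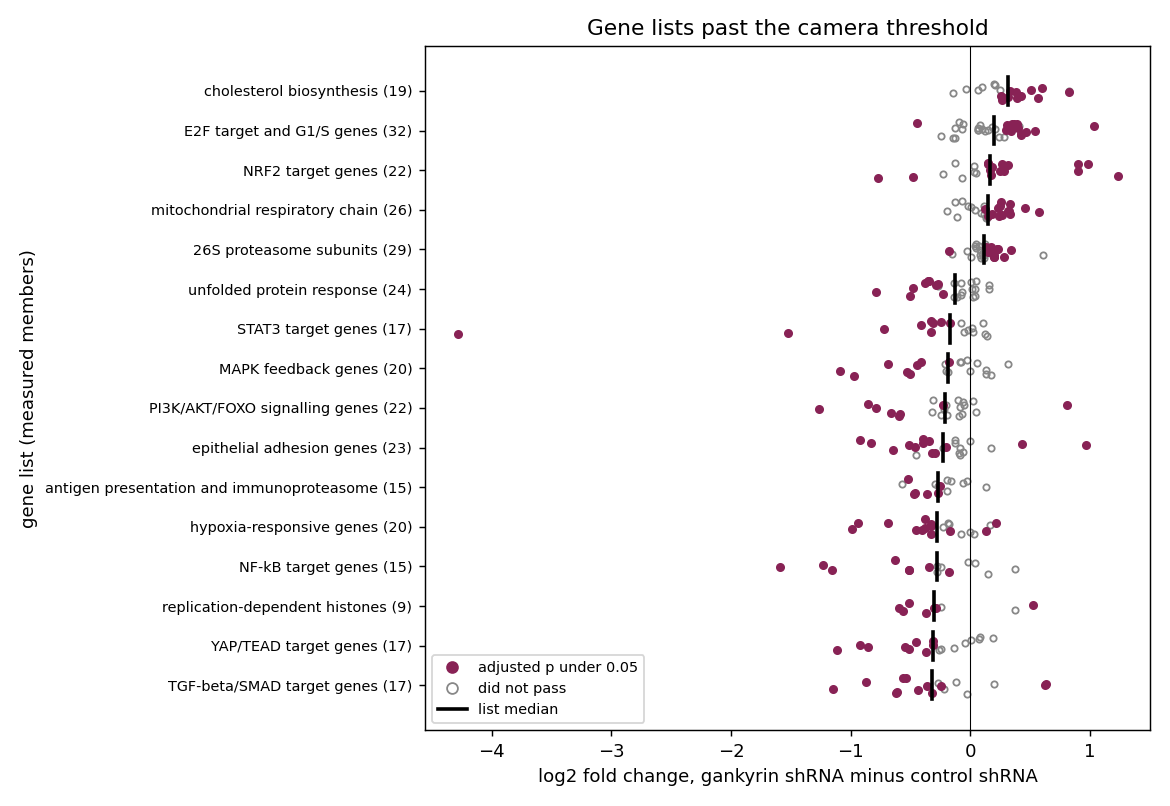
Log2 fold change, gankyrin shRNA minus control shRNA (x axis), of each measured member of 16 lists past the camera threshold (y axis, number of members in brackets); filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. Medians run from -0.32 for TGF-beta/SMAD targets to 0.32 for cholesterol synthesis, and FGL1 lies far to the left at -4.28.

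The other lists did not pass camera, although single members changed. Of 18 Wnt/beta-catenin targets 7 fell and 2 rose (7 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.147), among them CCND1 and the transcription factor PROX1 at -1.65 ± 0.18. Of 21 interferon-stimulated genes 8 fell and 3 rose (8 and 3 adjusted over the list alone, median -0.17, camera adjusted p = 0.159), with ISG15 at -0.73 ± 0.06. Heat shock genes had 7 falls and 1 rise among 18 (8 and 3 adjusted over the list alone, median -0.08, camera adjusted p = 0.187), with the inducible chaperone HSPA6 at -1.88 ± 0.17; without control replicate 3 this list passed as lower (camera adjusted p = 0.0307). Over all 6 arrays it had an adjusted p = 0.546 with an estimated correlation. Targets of p53 had 4 rises and 4 falls among 25 (4 and 5 adjusted over the list alone, median 0.03, camera adjusted p = 0.677), or 7 rises and 4 falls without control replicate 3. Differentiation genes of enterocytes and goblet cells had 2 rises and 3 falls among 19 (2 and 3 adjusted over the list alone, median 0.00, camera adjusted p = 0.821); the keratin KRT20 was at -0.66 ± 0.06 and CEACAM5 at -1.14 ± 0.11 on one probe set, its other being at -0.01 and not passing. Mesenchymal genes had 2 rises and 2 falls among 14 (2 and 2 adjusted over the list alone, median 0.05, camera adjusted p = 0.849), with FN1 (fibronectin) at -0.36 ± 0.05, or at -0.15 with its probe sets averaged, where it did not pass (limma adjusted p = 0.306). The CDK inhibitor and RB family list had 2 falls and 0 rises among 8 (2 and 1 adjusted over the list alone, median 0.00, camera adjusted p = 0.821), which were CDKN1C at -1.29 ± 0.21 and CDKN2B at -0.61 ± 0.10. Averaging probe sets ended the CDKN2B call (-0.31, limma adjusted p = 0.133), its other probe set being at -0.01. Glycolysis had 2 rises and 5 falls among 18 (3 and 5 adjusted over the list alone, median 0.02, camera adjusted p = 0.948), with the glucose transporter SLC2A1 at -0.56 ± 0.05. Apoptosis regulators had 7 falls and 0 rises among 24 (7 and 2 adjusted over the list alone, median -0.08, camera adjusted p = 0.257), led by BIK at -0.67 ± 0.07. Autophagy and lysosome genes had 6 falls and 1 rise among 28 (8 and 4 adjusted over the list alone, median -0.01, camera adjusted p = 0.821), led by the protease CTSB at -1.11 ± 0.07. Without control replicate 3 the autophagy list had 7 falls and 5 rises, the apoptosis list 9 and 2 and the glycolysis list 5 and 4.

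Fatty acid synthesis had 3 rises and 1 fall among 14 genes (3 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.180), with the acetyl-CoA carboxylase ACACA at 0.43 ± 0.05 (0.23 with its probe sets averaged). Without control replicate 3 the counts were 5 rises and 1 fall. ATF4 targets had 5 rises and 3 falls among 27 (5 and 4 adjusted over the list alone, median -0.02, camera adjusted p = 0.510), ribosome biogenesis 2 and 2 among 25 (1 and 1 adjusted over the list alone, median -0.06, camera adjusted p = 0.564; 3 and 6 without control replicate 3), and the RNAi machinery 0 and 3 among 12 (0 and 3 adjusted over the list alone, median -0.15, camera adjusted p = 0.204). Of 34 cytosolic ribosomal protein genes 2 rose and 0 fell (median 0.00, camera adjusted p = 0.435), and 0 passed adjusted over the list alone. With median centring the ribosomal protein list passed (camera adjusted p = 0.0244); on the deposited scale it had an adjusted p = 0.529 with an estimated correlation. Markers of other cell types did not pass camera as lists. Fibroblast markers (7 measured genes) had a median of 0.13 (camera adjusted p = 0.204), but limma's fry called that list (adjusted p = 0.04685). For leukocytes (6 genes), liver (6 genes) and endothelium (4 genes) the medians were 0.12, 0.02 and -0.02. Their camera adjusted p-values were 0.375, 0.821 and 0.909. The serine protease gene FAP, at 0.84 ± 0.13 from a control mean of 4.28 at the low end of the scale, was the 1 member of these 4 lists that passed in limma, over all genes or over its list alone. The FAP call was lost with unmoderated variances (adjusted p = 0.0587). Without control replicate 3 the leukocyte marker ITGAM also rose (0.46, limma adjusted p = 0.0024). Mean, median and camera's direction did not share a sign in the p53, ATF4, enterocyte, CDK inhibitor, G2/M, ribosomal protein, endothelial and glycolysis lists.

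Control replicate 3 stood apart in signs of cRNA quality. The log2 difference between the 3' and 5' probe sets of ACTB (beta-actin) was 1.82 on that array and 0.50 ± 0.04 (SD) on the other 5, and for GAPDH it was 0.56 against -0.06 ± 0.05. Without that array 4161 genes passed, 1808 higher and 2353 lower. Of the 3189 genes called on all 6 arrays, 3137 kept their call and direction without it. A further measure moved with the groups: the 18S ribosomal RNA control probe sets were higher on all 3 knockdown arrays than on any control array, although the 5' probe set, at 0.82, did not pass (limma adjusted p = 0.0715 over the control probe sets). The 3' probe set went from 6.16 ± 0.13 to 7.44 ± 0.13 (SD, n = 3 each), with a limma adjusted p of 0.00129 over the control probe sets. The 28S ribosomal RNA probe sets did not pass, at 0.04 (3'), 0.08 (5') and 0.44 (middle), with limma adjusted p-values of 0.649, 0.584 and 0.0715. The middle 28S probe set, like the 18S ones, was higher on all 3 knockdown arrays than on any control array.

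**Figure D3:**
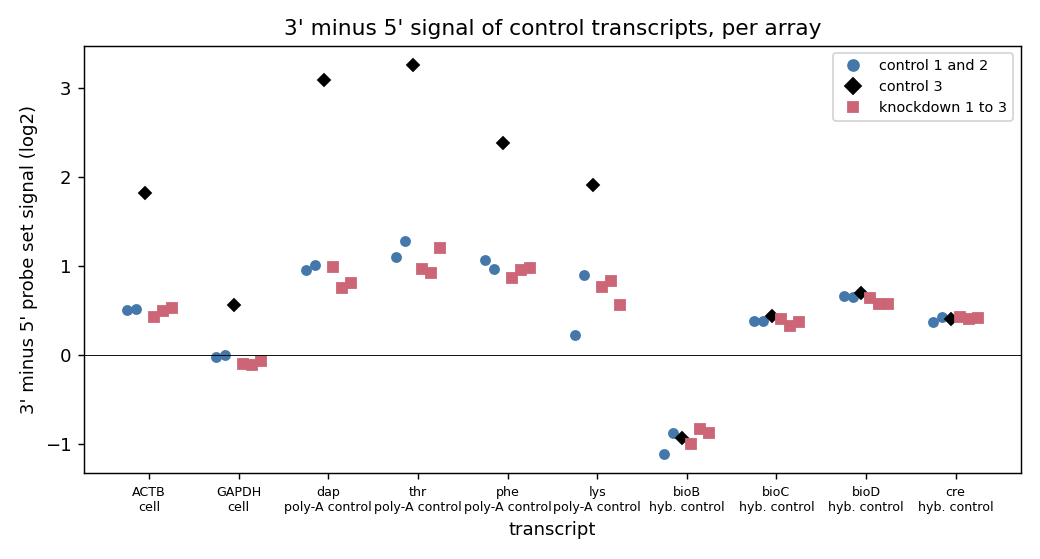
Difference between the log2 signals of the 3' and 5' probe sets (y axis) of transcripts from the cells, of poly-A control transcripts and of hybridisation controls (x axis) on each of the 6 arrays. Control replicate 3 (black diamonds) lies above the other 5 arrays for ACTB, at 1.82, and for dap, at 3.09, while for the hybridisation controls it exceeds the mean of the other arrays by at most 0.076.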

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

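The tests on 18S ribosomal RNA were chosen only after its difference between the groups had been seen. The control probe sets for 18S ribosomal RNA, which take no part in the gene comparison, were higher on every knockdown array than on every control array, by 1.29 on the log2 scale for the 3' probe set and 0.787 for the middle one. A shift of scale between the groups is argued against by the hybridisation controls, whose mean difference was -0.0637, and control replicate 3 alone is argued against because the smallest of the 3 differences was 0.737 without it. Carry-over of ribosomal RNA into the labelling reaction and a change of 18S in the cells cannot be told apart, since no measure of ribosomal RNA input per array was used here; within the control arrays the 3' probe set spanned 0.26. Of the 28S probe sets none passed (0.04, 0.08 and 0.44), but the middle one, like 18S, was higher on every knockdown array, so the explanation stays open.

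Among 5755 probe sets without a single gene name that passed the filter on signal, 121 were higher and 283 lower after knockdown (limma with adjustment over all probe sets tested). Over all 32759 probe sets in that fit, 1326 were higher and 2141 lower. The 5755 include probe sets paired with several genes, so some may read genes already analysed.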

How the results depend on the processing

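The alternatives were fixed before the data were examined, except the counts of list members that rose or fell without control replicate 3 and the matched random lists, which were added after the data had been examined. PSMD10 stayed lower and past the threshold under each alternative fit run, between -3.81 and -3.67 when single arrays were left out and at -3.74 (adjusted p = 1.25e-07) with the replicate number as a block. The block changed no call of a list or named gene and gave 3049 genes. Deviations of same-numbered arrays correlated at 0.0198, 0.108 and -0.00551, and only those of replicate 2 correlated best with their own number. With 3 arrays per group this cannot exclude pairing, and the main fit used the numbers only as names. The count of 3189 genes depended on the variance model: 1061 (484 higher, 577 lower) with unmoderated variances, 5153 (2093 and 3060) with array weights, and 1455 (540 and 915) at an adjusted p under 0.01, where a stricter threshold itself lowers the count. Leaving out single arrays gave 1732 to 4161 genes, 613 to 1808 higher and 1071 to 2353 lower. Without merging probe sets of a gene, 201 changed at least 2-fold, as more features were tested. NFIL3 missed the threshold with median centring (-0.22, adjusted p = 0.0633), with no intensity trend (-0.26, 0.0621) and with unmoderated variances (-0.26, 0.132); without single arrays it ranged from -0.33 to -0.20 (adjusted p 0.0137 to 0.112), and the cause was not tested. Lists past the threshold numbered 14 to 18 without single arrays and 0 with an estimated correlation. Limma's fry called 22. Lists that fry called and camera did not were apoptosis (fry adjusted p = 0.01058), interferon (0.04115) and ribosome biogenesis (0.04949). The same held for the Wnt, heat shock and fibroblast lists (fry adjusted p = 0.04685 each). Leaving out the lowest 60% of probe sets ended the unfolded protein, TGF-beta and MAPK calls (adjusted p = 0.0575 each), averaging a gene's probe sets ended these 3 and the STAT3 call, camera on ranks the MAPK call (0.0588) and fry the PI3K call (0.0874). With the mean of a gene's probe sets BCL2L1 turned to 0.04, and 14 of 127 named genes lost their call, against 7 with no intensity trend and 32 with unmoderated variances, among them CXCL1, LCN2, NDRG1, IRS1, MANF, HYOU1, HSPA5 and EBP. Avoiding probe sets ending in _x_at or _s_at turned ATP5F1C to -0.29 and SQSTM1 to 0.04; here the probe set differs. Pseudocounts were not run, since the values are logarithms. No detection calls were used here, so signals near 4.31 or below are only bounds on the level.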

Other observations

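The tests on the 5' signals of control replicate 3 and the comparison of E2F with G2/M genes were chosen after their results had been seen. Outside the fixed lists, 209 families of at least 8 measured genes sharing a symbol root were tested with camera, and 1 passed: the symbols that begin with MRPL, mostly proteins of the large mitochondrial ribosomal subunit. Of 49 measured members, which include the antisense RNA MRPL20-AS1 (0.03, not passed), 18 rose and 2 fell, with a median log2 fold change of 0.12 (camera adjusted p = 0.000149, adjusted p = 0.996 with an estimated correlation). MRPL1 rose by 0.49 ± 0.06 (SE), MRPL39 by 0.40 ± 0.06, MRPL15 by 0.38 ± 0.05 and MRPL3 by 0.29 ± 0.04. The MRPL family also passed without control replicate 3 (camera adjusted p = 0.000581). The symbols that begin with MRPS, mostly proteins of the small mitochondrial ribosomal subunit, went the same way but did not pass. Of 27 measured members 6 rose and 2 fell, with a median of 0.07 (camera unadjusted p = 0.00511, adjusted p = 0.1525). The rise is therefore not shown to be particular to the large subunit.

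The mean log2 signal of the E2F target and G1/S genes relative to that of the G2/M genes was higher on all 3 knockdown arrays (-0.28, -0.31 and -0.12) than on all 3 control arrays (-0.42, -0.44 and -0.56). The difference of 0.233 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Of the 9 replication-dependent histone genes 6 fell and 1 rose, with a median of -0.30 (camera adjusted p = 0.0358, adjusted p = 0.452 with an estimated correlation). Whether these probe sets read the total level of histone transcripts, or follow S phase, was not tested. The list is therefore not set against the E2F genes. The share of cells in each phase was not analysed here.

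The lists of cholesterol synthesis, respiratory chain, proteasome, NRF2 and E2F genes were higher after knockdown in camera with its preset correlation. None of the 5 passed with an estimated correlation (adjusted p = 0.447 to 0.452 with an estimated correlation). A trend with mean signal is argued against, since at most 0.22% of 10000 random lists matched on mean signal reached the median of any of the 5 lists. Control replicate 3 alone and the scaling between arrays are argued against as well: at the preset correlation the highest camera adjusted p of the 5 lists was 2.11e-05 without that array and 4.35e-05 under median centring or quantile normalization. Given those values correlation among the genes of a list stays open, as does the knockdown itself or an effect of the hairpin on other transcripts, for which no additional hairpin was analysed here.

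Control replicate 3 had low 5' signals. Hybridisation or scanning is argued against by the pre-labelled hybridisation controls, whose excess of the 3' over the 5' signal was only 0.036 over the other 5 arrays. Degraded cell RNA alone is argued against by the poly-A control transcripts, which do not come from the cells and had a mean excess of 1.75. The labelling reaction of that array is a candidate explanation, since the smallest excess among the 4 poly-A controls was 1.248, beside 1.32 for ACTB and 0.62 for GAPDH from the cells; no biological explanation was tested.

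The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3189 genes and 17 lists and was the 1 split that gave as many of either. The highest of the other splits gave 0 genes and 10 lists. Every other split mixes knockdown and control arrays on each side. The group difference then adds to the spread within a side, so few gene calls are built in there.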
